A study of Mus musculus with 4 samples.

How the data were processed

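Splenic CD4+CD25- T cells of db/db and db/+ mice, stimulated for 12 h, were measured on 4 one-colour arrays, 1 per pool of 3 mice, with 2 pools per group. Per the series text there were 2 independent experiments with 3 mice per group pooled in each, but the labels do not tie the replicate numbers to the experiments, so the samples were grouped by genotype alone. The labels call the phenotype leptin-deficient in the sample characteristics and leptin-receptor-deficient in the series title; db/db mice are the latter.

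The deposited raw table gives the median foreground intensity of each feature on a linear scale, without background subtraction or normalization, per the file headers. The deposited value table of the authors holds log2 values, and it matched log2 of the raw intensities after quantile normalization with no background correction to within 5.00e-09 in every array. The submitters' processing notes name limma and give no further steps. The number of arrays limits the precision: with 2 against 2 pools an exact permutation test of a gene cannot go below p = 0.333, so the tests below rest on limma's spread pooled over features.

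The row numbers of the deposited tables are not the feature numbers of the platform annotation, and the tables name no genes. The position of each annotated feature was therefore inferred from the data by comparing 24 layouts of the array grid, after the values had been seen. In the chosen layout, 2293 features of 218 transcript accessions with at least 8 features each differed within an accession by a median absolute deviation of 0.157 log2 units, against 0.893 in the next best layout and with row numbers taken as feature numbers. Every gene name here rests on that layout. The annotation listed 33709 of 45220 features, 33653 with 1 symbol and 56 with several, for 19088 genes, and gives no probe identity, so replicate spots of a probe were not averaged as had been planned and each feature was tested alone.

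In R 4.3.3 with limma 3.58.1, intensities were background corrected by normexp with an offset of 50 on the foreground, log2 transformed and quantile normalized, and each gene feature was tested for db/db against db/+ with a linear model and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over 33709 features and a threshold of 0.05. This fit, its alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Of 46 fixed lists, 44 had at least 5 measured members and were tested by camera with a preset correlation of 0.01 on the brightest feature per gene, adjusted over the lists, with an estimated correlation and fry beside it. Of 1112 list entries 1095 were resolved to a gene and 1011 had a feature. Counts of list members include members at background. A group was called background where both of its pools lay below the median of 7.55 over gene features, and a gene where both group means did, since the table marks no control spots, and a fold against such a group is given as at least the ratio to that level.

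Stretches of neighbouring spots departed between arrays, and the rule that left them out was chosen after seeing the data. A scan line of 266 spots was left out where more than 5% of its spots on any array lay over 2 log2 units from the median of the other 3 arrays, as in 40 of 170 lines. Windows of 15 spots with at least 3 such spots were added to the rule once the largest changes had been seen to be neighbours on the grid. An attempt to realign the misread lines by shifting them was dropped. On the lines left out, 1876 spots were off on 1 array, 54 on 2 and 334 on all 4, and in 282 of the 334 both arrays of 1 genotype lay above both of the other. The rule is not independent of the comparison, since a change of over 2 log2 units between the genotypes puts a spot off on all 4 arrays. It also removes spots for their spread, which lowers the spread left for the test. With splits by genotype not counted 38 lines were left out, and 33 when only differences within a genotype counted, both added later. It left out 8242 gene features, or 24.5%, kept 25467 and removed every feature of 2943 genes. The fold changes of kept features did not change, and both fits are reported.

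The named genes were Lepr, the 10 largest rises and the 10 largest falls among called genes above background with both db/db pools beyond both db/+ pools, up to 3 members of each list with the smallest unadjusted p, and 14 fixed genes. The same rule was applied again with the misread stretches left out, after the data had been seen. A gene is given by its brightest feature outside misread stretches.

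On simulated data with log2 changes of 1, 2 and 3, the fit called 0%, 25.4% and 60.6% of changed features, and 46.3%, 77.6% and 83.3% with the misread stretches left out. The latter drew on the spreads of kept features, from which the rule had already removed spots of large spread. The rule was not applied to the simulated arrays, so the higher shares do not show a gain in power. Alternatives were other background corrections, median scaling and cyclic loess, the authors' values, dim features left out, a replicate block, an intensity trend with a robust fit, another threshold, genes in place of features, the mean over all features of a gene for the lists, and each array left out in turn. Alternatives added after seeing the data varied the misread rule, the layout and the lists tested, tested all features of the arrays, or averaged the features of one accession. Random lists matched on intensity were drawn in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with Matplotlib 3.10.9.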

Results

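Gene expression was measured in splenic CD4+CD25- T lymphocytes of C57BL/6 mice after 12 h of stimulation with antibodies against CD3 and CD28, the signal pair that starts T cell activation in culture. Cells came from db/db mice, which are homozygous for a mutation of the leptin receptor gene Lepr and become obese and diabetic, and from db/+ mice, which carry a functional copy and served as the wild-type group. Each group held 2 samples, each a pool of cells from 3 mice. Each of the 4 pools was hybridised to its own one-colour Agilent array of 45220 features, of which 33709 were assigned to genes. The median raw intensity was 254 and 151 in db/+ pools 1 and 2 and 102 and 176 in db/db pools 1 and 2. In that order, 50, 7, 2 and 112 features stood at the scanner maximum of 65535. The normalized log2 intensities of gene features correlated across features, which are not independent replicates, at r = 0.976 between the db/+ pools, 0.972 between the db/db pools and 0.946 to 0.967 between groups.

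The comparison asked how the absence of leptin receptor signalling alters the expression profile of stimulated effector T cells. In db/db cells the transcripts of the cytokines Il2 and Il3 were lower than in db/+ cells and those of Il24 were higher. With a preset correlation between genes, gene groups of ribosome biogenesis and amino acid supply were called lower, and those of cell division, cholesterol synthesis, the interferon response, neutrophils and B cells higher. None of these group calls held with an estimated correlation (adjusted p = 0.465 to 0.690). Transcripts of the Y chromosome were seen in the db/db pools and not above background in the db/+ pools.

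Over all gene features, 336 of 33709 differed (limma, adjusted p below 0.05), 195 higher and 141 lower in db/db, while 6578 had an unadjusted p below 0.05. With the replicate number as a block the count was 0. The split between higher and lower depended on the scaling, with 126 higher and 270 lower after median scaling and 58 higher and 91 lower after cyclic loess. Of the 336 called features 160, or 47.6%, lay in stretches of the arrays where many spots departed between arrays, taken as misread. With those stretches left out, a choice made after seeing the data, 2089 of 25467 features differed, 1705 higher and 384 lower, and 176 features were called in both fits. With the replicate block as well the count was 445. The arrays were not normalized again without the stretches, and median scaling and cyclic loess were not run there. The split of the 2089 was therefore not checked against the scaling. The count fell to 0 in both fits when any of the 4 arrays was left out. Below, the first adjusted p of a gene is from the fit over all gene features and the second from the fit with the misread stretches left out. The log2 fold change of a feature is the same in both. The features of a gene were read on the same 4 arrays, so their agreement is not replication. For accessions with at least 8 features, agreement within an accession also guided the choice of layout.

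**Figure D1:**
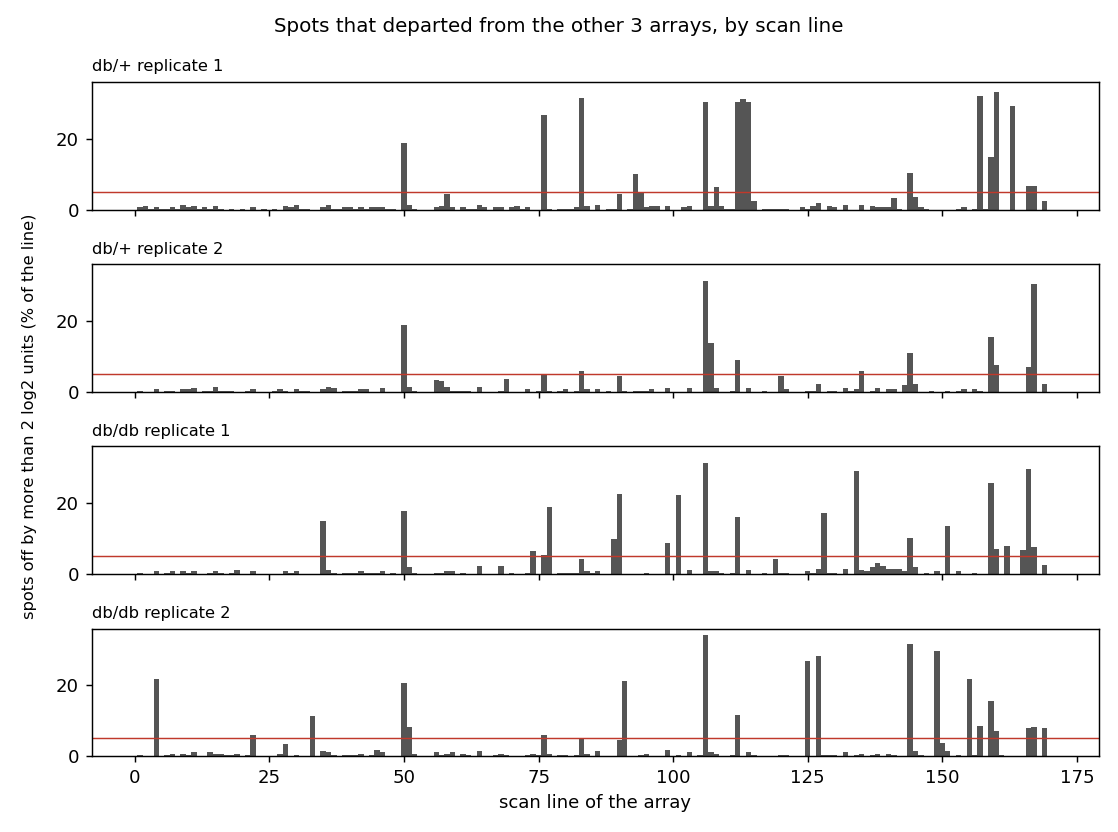
Percentage of the 266 spots on each of the 170 scan lines that lay more than 2 log2 units from the median of the other 3 arrays, with 1 panel per array and the 5% line drawn in red. Most lines lie near the median of 0.376%, while some lines reach up to 34.2%.

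Lepr itself could not check the labels. All 10 of its features outside misread stretches lay at background in every pool. The brightest read 6.27 ± 0.04 in db/+ and 6.33 ± 0.13 in db/db on the log2 scale (SD, n = 2; adjusted p = 0.820 and 0.823), below the median of 7.55 over gene features. The db mutation alters splicing of the receptor transcript, so a feature outside the affected exon would not report it.

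Among the T helper cytokines, Il2, the growth factor of activated T cells, fell from 14.72 ± 0.07 to 12.58 ± 0.26 (SD, n = 2 pools per group), a 4.43-fold lower level in db/db (adjusted p = 0.0486 and 0.0148). All 8 of its features outside misread stretches were called lower in the second fit. Il3, a haematopoietic growth factor made by activated T cells, fell 6.28-fold, from 11.63 ± 0.03 to 8.98 ± 0.31 (adjusted p = 0.0444 and 0.0139). Il24, a cytokine of the interleukin 10 family, rose 8.69-fold, from 7.96 ± 0.25 to 11.08 ± 0.17 (adjusted p = 0.0406 and 0.0129). Il9 was 8.47-fold and Il22 2.69-fold higher in db/db, past the threshold only with the misread stretches left out (adjusted p = 0.0621 and 0.0174 for Il9, 0.0522 and 0.0156 for Il22). Ifng, the main cytokine of Th1 cells, differed by -0.46 in log2 on its brightest feature (adjusted p = 0.119 and 0.0627), Tnf by -0.65 (0.139 and 0.0622) and Il4 by -0.67 (0.101 and 0.0422). In the second fit 3 of 8 Ifng features, 2 of 9 Tnf features and 3 of 8 Il4 features were called lower. Il17a differed by 0.10 (0.672 and 0.668), a sign that turned under median scaling and cyclic loess. Of 27 measured cytokines of the list 1 rose and 2 fell, or 3 and 11 adjusted over the list alone. With the misread stretches left out 3 of 25 rose and 8 fell, among the latter Cd40lg, which was at background in every pool. The list was called lower by camera (adjusted p = 0.00343), with adjusted p = 0.690 with an estimated correlation, and lost the call without db/+ replicate 2. Its median log2 fold change was -0.42, and -0.23 with the misread stretches left out.

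The T cell activation markers were shifted downwards in db/db (camera adjusted p = 0.00129; adjusted p = 0.550 with an estimated correlation), with a median log2 fold change of -0.44. None of the 27 members passed over all genes and 5 fell adjusted over the list alone, while 3 of 22 fell with the misread stretches left out, 1 of them Cd40lg at background. Il2ra, the high-affinity subunit of the interleukin 2 receptor, read 14.99 ± 0.13 in db/+ and 14.32 ± 0.07 in db/db (adjusted p = 0.101 and 0.0419), and 1 of its 4 features was called in the second fit. Cd69, an early activation marker, differed by -0.72 (adjusted p = 0.236 and 0.121). The memory and effector T cell genes were shifted upwards (median 0.49; camera adjusted p = 1.73e-05; adjusted p = 0.690 with an estimated correlation), with none of 29 passing over all genes and 10 rising adjusted over the list alone. With the misread stretches left out 7 of 28 rose, among them Crip1 (1.12 in log2), Lgals1 (1.28) and Vim (2.23).

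Genes of ribosome biogenesis and direct growth control by MYC were lower in db/db (median log2 fold change -0.63; camera adjusted p = 1.25e-15; adjusted p = 0.465 with an estimated correlation). Of 31 members 1 fell over all genes, namely Fbl on a feature in a misread stretch, and 22 fell adjusted over the list alone. With the misread stretches left out 14 of 28 fell and none rose. Polr1b, a subunit of RNA polymerase I, read 13.91 ± 0.10 in db/+ and 12.82 ± 0.02 in db/db, a 2.12-fold lower level (adjusted p = 0.0576 and 0.0190). Nolc1, a nucleolar phosphoprotein, was 1.84-fold lower (adjusted p = 0.0613 and 0.0216). Myc itself read 15.80 ± 0.07 and 15.20 ± 0.03, 1.52-fold lower (adjusted p = 0.0903 and 0.0393), and 3 of its 10 features were called in the second fit.

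Targets of ATF4, which serve amino acid synthesis and uptake, were lower as well (median -0.63; camera adjusted p = 1.28e-06; adjusted p = 0.514 with an estimated correlation). None of 22 passed over all genes and 12 fell adjusted over the list alone. In the fit without misread stretches 8 of 21 fell. Mthfd2, a mitochondrial folate enzyme, was 2.76-fold lower (adjusted p = 0.0658 and 0.0202). Psph, the last enzyme of serine synthesis, was 2.28-fold lower, from 15.82 ± 0.11 to 14.63 ± 0.07 (adjusted p = 0.0574 and 0.0183). The proteasome list was called lower (median -0.30; camera adjusted p = 0.00291; adjusted p = 0.550 with an estimated correlation) with none of its 30 members past the threshold in either count, and lost the call under cyclic loess. Its median was -0.14 with the misread stretches left out. Cytosolic ribosomal protein genes went the other way (median 0.33; camera adjusted p = 0.00854; adjusted p = 0.684 with an estimated correlation), with none of 56 passing over all genes or adjusted over the list alone and 3 of 47 rising with the misread stretches left out. These were Rps13 (0.93 in log2), Rps3 (0.96, on 1 of its 2 features) and Rps24 (0.90), whose 2 features were called in opposite directions. That call was lost without either db/db pool, with dim features left out and with the mean over all features of a gene.

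Cell division genes were higher in db/db. In the mitosis list (median 1.20; camera adjusted p = 7.42e-09; adjusted p = 0.684 with an estimated correlation) 3 of 29 members rose over all genes and 22 adjusted over the list alone. The count was 13 of 25 with the misread stretches left out. Cdk1, the kinase that drives entry into mitosis, rose 3.57-fold, from 8.91 ± 0.04 to 10.75 ± 0.16 (adjusted p = 0.0422 and 0.0142). Top2a, a DNA topoisomerase of dividing cells, rose 3.89-fold (adjusted p = 0.0462 and 0.0148), although only 1 of its 2 features was called. In the list of G1 to S transition and DNA replication (median 0.72; camera adjusted p = 2.24e-04; adjusted p = 0.690 with an estimated correlation) 2 of 34 rose over all genes, and 18 rose and 2 fell adjusted over the list alone. The rises were 17 of 29 with the misread stretches left out. Cdc45, part of the replicative helicase, rose 3.72-fold, from 9.32 ± 0.13 to 11.22 ± 0.07 (adjusted p = 0.0409 and 0.0139). Gins2, another part of it, rose 3.69-fold (adjusted p = 0.0445 and 0.0146). Ccnd2, a G1 cyclin, differed by -0.47 (adjusted p = 0.155 and 0.0818). The cell cycle inhibitor Cdkn1b differed by 0.88 on its brightest feature (adjusted p = 0.0772 and 0.0283), but its 5 features disagreed, with a median of -0.99.

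Genes of cholesterol and fatty acid synthesis were higher in db/db (median 0.71; camera adjusted p = 7.91e-05; adjusted p = 0.588 with an estimated correlation). Of 27 members 1 rose over all genes, and 16 rose and 1 fell adjusted over the list alone, while 14 of 22 rose with the misread stretches left out. Stard4, a cholesterol transfer protein, rose 2.64-fold, from 9.57 ± 0.00 to 10.97 ± 0.06 (adjusted p = 0.0409 and 0.0146). Tm7sf2, a sterol reductase, rose 3.04-fold (adjusted p = 0.0442 and 0.0146). Scd2, a fatty acid desaturase, was 4.19-fold higher, past the threshold only with the misread stretches left out (adjusted p = 0.0639 and 0.0185). The list of fatty acid oxidation and PPAR targets was shifted by less (median 0.37; camera adjusted p = 0.00863; adjusted p = 0.690 with an estimated correlation), with none of 28 passing over all genes, 1 rising adjusted over the list alone and 3 of 25 with the misread stretches left out. Its call was lost under median scaling and without db/db replicate 1.

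Interferon response genes were higher in db/db (median 0.79; camera adjusted p = 3.15e-05; adjusted p = 0.514 with an estimated correlation). Of 29 members 4 rose over all genes, and 17 rose and 1 fell adjusted over the list alone, while 11 of 21 rose with the misread stretches left out. Usp18, a protease induced by type I interferon, rose 4.02-fold, from 11.66 ± 0.08 to 13.67 ± 0.02 (adjusted p = 0.0324 and 0.0124). Stat2, a transcription factor of the same pathway, rose 3.26-fold (adjusted p = 0.0377 and 0.0133) and Mx2, an antiviral GTPase, 2.81-fold (adjusted p = 0.0402 and 0.0139).

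Markers of other cell types differed between the same pools as each of the gene groups above. The neutrophil list was higher in db/db (median 1.99; camera adjusted p = 7.80e-06; adjusted p = 0.684 with an estimated correlation), with 4 of 16 rising over all genes and 11 adjusted over the list alone. In the fit without misread stretches 8 of 14 rose. Ltf, a granule protein, rose 10.8-fold, from 8.27 ± 0.01 to 11.70 ± 0.01 (adjusted p = 0.0290 and 0.0104). Ngp, another granule protein at background in both db/+ pools, rose at least 7.50-fold (adjusted p = 0.0290 and 0.0124). The B cell list was higher (median 0.65; camera adjusted p = 1.17e-04; adjusted p = 0.684 with an estimated correlation), with 2 of 19 rising over all genes, 9 adjusted over the list alone and 7 of 19 with the misread stretches left out. Bank1, a B cell adaptor, rose 2.42-fold (adjusted p = 0.0471 and 0.0156), on 1 of its 2 features. The macrophage and monocyte list (median 0.45; camera adjusted p = 7.23e-04; adjusted p = 0.684 with an estimated correlation) and the MHC class II list (median 0.81; camera adjusted p = 0.00613; adjusted p = 0.744 with an estimated correlation) were called higher. None of 22 and none of 12 members passed over all genes, 8 and 4 rose adjusted over the list alone, and 4 of 17 and 4 of 11 rose with the misread stretches left out. The second list lost its call without db/db replicate 2. Cd8a marks CD8 T cells, which the purification was meant to remove. It rose 2.90-fold, from 11.76 ± 0.32 in db/+ to 13.30 ± 0.04 in db/db (adjusted p = 0.0751 and 0.0236), on all 11 features in the second fit. The NK cell, dendritic cell, plasma cell, CD8 T cell, erythroid, platelet and stromal lists were not called. Leaving out db/+ replicate 1 gave a call for the erythroid list, lower in db/db, and leaving out db/+ replicate 2 for the CD8 T cell and platelet lists, higher in db/db.

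Some transcripts that mark the sex of an animal separated the groups. Eif2s3y and Kdm5d, both encoded on the Y chromosome, were at background in both db/+ pools and rose at least 79.1-fold and at least 24.7-fold in db/db (adjusted p = 0.0290 and 0.0115, and 0.0290 and 0.0104). Xist and 3 more Y-linked genes were looked up after these values were seen. Uty was at background in both db/+ pools and at least 1.59-fold higher in db/db (adjusted p = 0.0552 and 0.0156), while Zfy1 and Usp9y were at background in all 4 pools. Xist, the RNA that silences the second X chromosome of females, read 14.33 and 13.88 in db/+ pools 1 and 2 and 10.06 and 6.60 in db/db pools 1 and 2 (adjusted p = 0.151 and 0.0575). No sex is given in the labels, and the separation by Eif2s3y, Kdm5d, Uty and Xist was complete over the 4 pools.

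**Figure D2:**
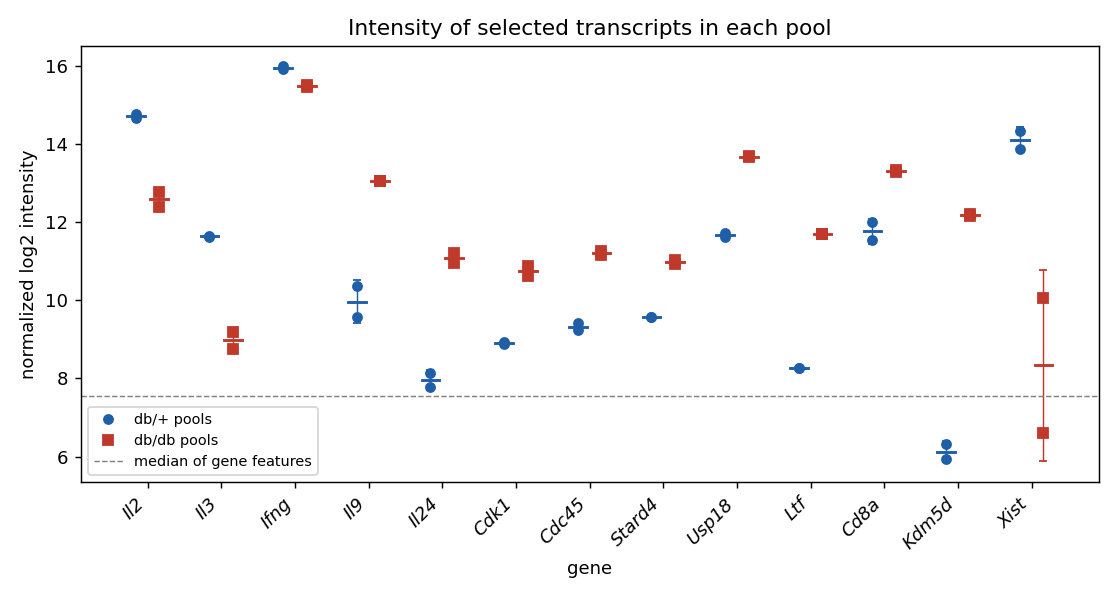
Normalized log2 intensity of 13 transcripts in each of the 4 pools, with db/+ pools as blue circles and db/db pools as red squares. Short horizontal lines are group means, error bars are SDs (n = 2), and the dashed line is the median of 7.55 over gene features; Il2 and Il3 lie lower in db/db, Ltf and Kdm5d higher, and Xist differs by -5.77 between the group means with the widest spread in db/db.

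Many of the largest changes by the fixed rule lay in misread stretches. Among the 10 largest rises over all gene features were Eif2s3y, Kdm5d, Ngp, Ltf and Il24, named above, and Chil4, a chitinase-like protein, which rose at least 8.37-fold, Fpr2, a chemoattractant receptor of myeloid cells, which rose 10.1-fold, and Igsf23 on 1 of its 2 features, which rose 8.70-fold. The remaining 2 rises, Sigirr and Rad54l, and all 10 of the largest falls, of -5.87 to -4.31 in log2, Slc19a1, Emc2, Gcc2, Helz, Ipo7, Fam162a, Jagn1, Nfs1, Kctd20 and Trp53inp1, lay in misread stretches. Of these 12 genes 10 had another feature outside the stretches. For Rad54l, Helz, Jagn1 and Kctd20 that feature was at background in both group means and decides nothing. For the other 6 it was called in neither fit, with log2 fold changes between -0.61 for Trp53inp1 and 0.72 for Gcc2, although Slc19a1 lay close to background. Leaving out most of the falls depended on counting a split of the arrays by genotype as misread, since 9 of these 12 features were kept and called when such splits were not counted. A test added after this was seen compared features split by genotype with another feature of the same gene, outside the stretches and above background. On the 2 lines left out only through such splits, 58 features had a median log2 fold change of -3.89 and their other features one of -0.06, with 3 of 58 changed by more than 1 in the same direction. Among features outside the stretches that were split by genotype, all 24 with another feature had it changed by more than 1 in the same direction. These counts are of features and not genes. The other feature could itself be split by genotype, so 2 features of a gene could count each other. With the misread stretches left out the 10 largest falls were Fosb, H1f3, H1f5, Il3, Hspb1, C5ar2, Mmp13, H1f1, Rmrp and Il2. Of these Rmrp, the RNA component of an RNA-processing ribonuclease, fell at least 2.03-fold and passed in both fits (adjusted p = 0.0385 and 0.0130), as did Il2 and Il3. Fosb, an immediate early transcription factor, read 12.39 and 10.66 in db/+ pools 1 and 2 and was at background in db/db, at least 15.7-fold lower by the db/+ mean and at least 8.6-fold by the lower db/+ pool (adjusted p = 0.0951 and 0.0304). Also lower were the linker histone genes H1f5, by at least 4.30-fold, and H1f1, by at least 3.20-fold (second adjusted p = 0.0219 and 0.0287). H1f3, another linker histone gene, was called lower on 1 of its 2 features (second adjusted p = 0.0203), with a db/db mean of 7.41, near background. The same repeat added Gpnmb, on 1 of its 2 features, and Il9 to the rises.

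Several groups tied to leptin and T cell metabolism were not called. The leptin receptor signalling list had a median log2 fold change of 0.06 over 15 members (camera adjusted p = 0.745), with no member past the threshold over all genes or adjusted over the list alone. With the misread stretches left out 1 of 14 rose, its feedback inhibitor Socs3. It differed by 1.06 (adjusted p = 0.0849 and 0.0300) and Stat3 by 0.09 (0.814 and 0.799), with 1 of its 9 features called higher in the second fit. The mTOR pathway list had a median of -0.04 over 37 members (camera adjusted p = 0.745), with 1 member rising and 1 falling adjusted over the list alone. In the fit without misread stretches 2 of 37 rose and 2 fell, or 5 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.394). The rises were Pik3r1 and Sesn3, the latter named after its values were seen (0.80 in log2, on 1 of its 3 features), and the falls Eif4ebp1 and Deptor. Deptor, an inhibitor of mTOR, differed by -1.08 (adjusted p = 0.0955 and 0.0337), called lower on both of its features. Pik3r1, a regulatory subunit of PI3 kinase, rose 2.14-fold (adjusted p = 0.0464 and 0.0156), on 1 of its 3 features. Mtor differed by -0.16 (0.558 and 0.509) and Eif4ebp1, a translation repressor, by -1.50 (0.0692 and 0.0216). Glycolysis (median 0.29, camera adjusted p = 0.410), the TCA cycle (-0.05, 0.989) and oxidative phosphorylation (-0.04, 0.557) were not called, except for glycolysis under median scaling. Of 22 glycolysis members 1 rose over all genes, and 8 rose and 1 fell adjusted over the list alone. In the fit without misread stretches 6 of 21 rose, 1 of them at background, and the median was 0.17. The lactate exporter Slc16a3 rose 4.14-fold (adjusted p = 0.0445 and 0.0146) and the dehydrogenase Idh1 3.02-fold (0.0440 and 0.0146). The Th1, Th2, Th17 and regulatory T cell lists were not called, except for the last without db/+ replicate 1. Foxp3, the regulator of the last, read 10.38 ± 0.89 and 11.11 ± 0.09 (adjusted p = 0.503 and 0.381).

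**Figure D3:**
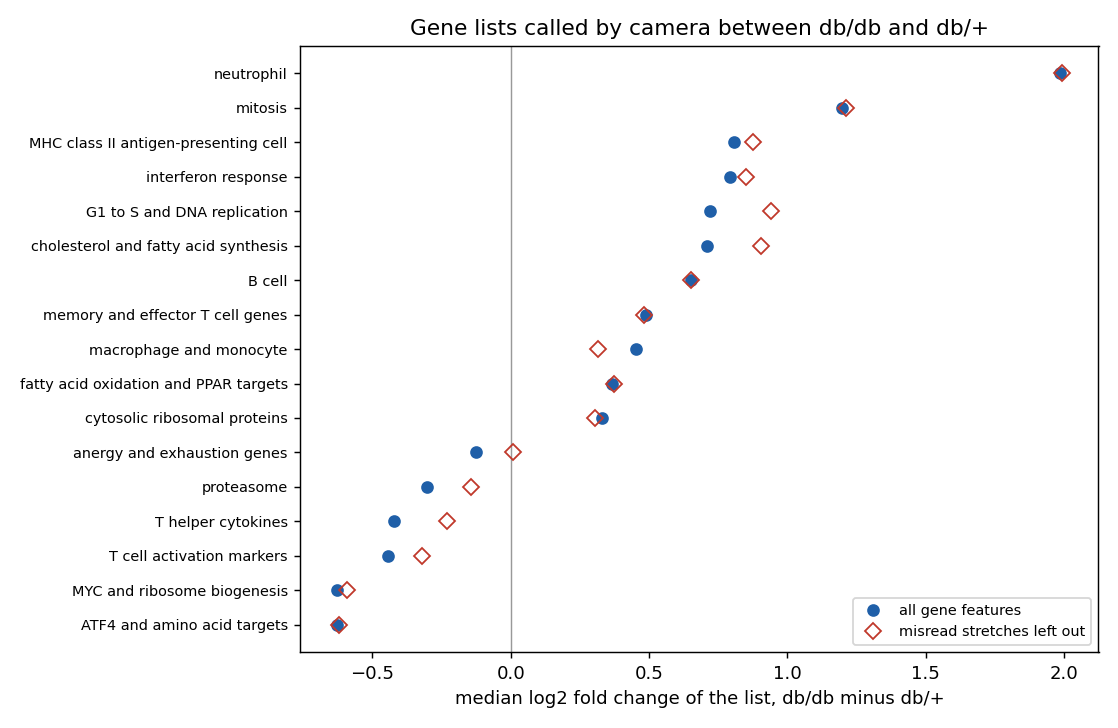
Median log2 fold change, db/db minus db/+, of the 17 gene lists called by camera with its preset correlation, as blue circles over all gene features and red diamonds with the misread stretches left out. The MYC and ribosome biogenesis list lies at -0.63 and -0.59 and the neutrophil list at 1.99 in both. None of the 17 held with an estimated correlation, a test that can hardly pass with 2 pools per group.

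In all, 17 of 44 tested lists were called, 11 higher and 6 lower in db/db, and 16 with the misread stretches left out. The anergy and exhaustion list (median -0.12; camera adjusted p = 0.0373; adjusted p = 0.684 with an estimated correlation; 2 rising and 4 falling adjusted over the list alone) lost its call with the misread stretches left out, with the mean over all features of a gene and when any 1 of the 4 arrays was left out. The median of the anergy and exhaustion list was 0.01 with the misread stretches left out. With an estimated correlation 0 of 44 lists passed, and by fry 4 did, namely MYC and ribosome biogenesis, ATF4 and amino acid targets, interferon response and cholesterol and fatty acid synthesis.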

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

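Features that the annotation does not list also differed between the genotypes. Over all features of the arrays, 18 of 11511 unlisted features were higher in db/db and 18 lower, and 20 of these 36 lay in misread stretches. With the misread stretches left out, a test chosen after the result was seen, 289 of 8692 were higher and 59 lower. What these features measure is not known here, and no explanation was tested.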

How the results depend on the processing

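The alternatives that leave out misread stretches, take row numbers as feature numbers or average the features of one accession were chosen after seeing the data. The 336 called features became 149 under cyclic loess (58 higher, 91 lower), 188 with dim features left out (64 higher, 124 lower), 1295 at an unadjusted p below 0.01 with an absolute log2 fold change above 1, and 0 with the replicate number as a block (5146 at an unadjusted p below 0.05). Leaving out any array gave 0 called features each time, with 5373 to 7565 at an unadjusted p below 0.05 and the lone pool of its group assumed to vary like the other group. With misread stretches left out the count was 2089, with lines alone 1992, at line thresholds of 3% and 10% 2391 and 1836, with splits by genotype not counted 2321, with only differences within a genotype counted 2173, or 2054 with lines alone, on the authors' values 1884, with an intensity trend and robust fit 2374, with the block 445, and 0 with any array left out. The number of called features is therefore not settled by these arrays. The 17 called lists became 0 with an estimated correlation, 0 with it and misread stretches left out, 4 by fry, 2 by fry with misread stretches left out, and 0 with row numbers taken as feature numbers. The mean over all features of a gene, planned, gave 15. Leaving out an array gave 14 to 18 called lists, and 15 to 19 with misread stretches left out. Rules that did not count splits by genotype called 16 or 17 lists, and of the 12 largest changes in misread stretches they kept and called 8 or 9. Of the 83 genes named in the text, 76 kept their sign in every setting. The sign turned for Il17a (-0.14 under median scaling, -0.12 under cyclic loess) and, when arrays were left out in turn, for Lepr (-0.039 to 0.15, negative without db/db replicate 1), Stat3 (-0.11 to 0.29, negative without db/+ replicate 2), and the features outside misread stretches of Ipo7 (-0.65 to 0.21, positive without db/db replicate 1) and Kctd20 (-0.11 to 0.024, positive without db/+ replicate 1 and, at 0.020, without db/db replicate 1), with the same values when misread stretches were left out as well. Kctd20 also turned under median scaling (0.077), as did Usp9y (0.051) and Zfy1 (0.086), both at background, and Zfy1 ran from -0.054 to 0.052 as arrays were left out, with or without misread stretches (positive without db/+ replicate 1 and, at 0.016, without db/db replicate 2). None of these was called, and the cause was not tested. Features below the median of 7.55 lie near background, where a change is compressed.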

Other observations

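Genes of resting T cells, which activation turns down, were partly higher in db/db. Txk, a kinase of T cell receptor signalling, was 2.67-fold higher (adjusted p = 0.0633 and 0.0197), Il7r, the receptor for interleukin 7, 2.65-fold (0.0921 and 0.0306), on 1 of its 3 features, and S1pr1, which guides exit from lymphoid tissue, 3.03-fold (0.106 and 0.0369). The list was not called by camera (adjusted p = 0.275), although 1 of 34 settings called it higher. None of 23 members passed over all genes, and 5 rose and 1 fell adjusted over the list alone. With the misread stretches left out 4 of 21 rose and 1 fell. Hspb1, a small heat shock protein, was 5.06-fold lower (adjusted p = 0.0696 and 0.0209), and its list was not called (adjusted p = 0.414).

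The tests against the cell shares and the sex of the mice, described next, were chosen only after the results were seen, and those against intensity before. The MYC and ribosome biogenesis list read lower in db/db. Bright features reading lower whatever the gene are argued against, since the list's median lay at percentile 0 of 10000 random lists matched on intensity. A lower share of T cells as a whole is argued against as well in these pools. The median of the T cell receptor signalling list lay 0.868 above that of the MYC list (SE 0.181, over list members and not pools). A lower share of activated CD4 T cells is not excluded, since the T cell receptor list does not separate them from resting or CD8 T cells. No biological explanation was tested, and genotype and sex both stay open, as does the loss of the MYC list's call with an estimated correlation.

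The same test did not set every called list apart. Of the 16 lists called with the misread stretches left out, 3 had a median inside the middle 95% of matched random lists, namely proteasome (percentile 5.70), fatty acid oxidation and PPAR targets (95.3) and macrophage and monocyte (89.8). Of the lists not called, 3 lay outside it, namely resting and naive T cell genes (98.4) and plasma cell (99.98) above and erythroid (0.06) below. Over all genes with the misread stretches left out, split into 10 bins by intensity, the median log2 fold change was -0.01 in the dimmest bin, 0.36 in bin 6 and 0.02 in the brightest.

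The neutrophil list read higher in db/db. Dim features reading higher whatever the gene are argued against by its percentile of 100 among matched lists. A lower share of CD4 T cells with all other cell types in unchanged ratios would raise their lists alike. The erythroid and macrophage medians of -0.39 (SE 0.423) and 0.32 (SE 0.33) argue against that, beside 1.99 (SE 0.643) for neutrophils. Their mean log2 intensities were 9.97 and 9.76. The MHC class II and plasma cell lists, at 0.88 (SE 0.13) and 0.92 (SE 0.578), lay closer to the neutrophil list. These SEs, too, are over list members. The NK cell list could not decide the point. The neutrophil median lay 1.84 above that of the NK cell list (SE 0.661, over list members and not pools). But the NK list shares members such as Nkg7 with the memory and effector T cell list. Its mean log2 intensity was 11.12, against 9.78 for the neutrophil list, so T cell signal could mask a rise. More neutrophils among the db/db cells, despite the selection for CD4+CD25- cells, could also account for the higher neutrophil list and stays open. Expression of neutrophil genes by the T cells stays open as well.

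The sex-linked transcripts above background, Eif2s3y, Kdm5d, Uty and Xist, parted the db/db from the db/+ pools. Sex of the mice in place of genotype as the source of the other called genes cannot be told apart from genotype, since 0 of the 4 pools had Y-linked transcripts at odds with its genotype label. Any of the differences between the groups could therefore come from sex, from genotype or from both. A different mix of cells in the pools was not ruled out either. The neutrophil, B cell, macrophage and MHC class II lists and Cd8a also read higher in db/db. Apart from the MYC list, the gene groups read in the T cells were not tested against the cell mix.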
